A study of Tetrahymena thermophila with 2 samples.

How the data were processed

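The series held 2 samples of wild-type CU428 *Tetrahymena thermophila*, a ciliate whose transcriptionally active macronucleus carries many copies of each of a large set of short chromosomes. Per the labels' protocols, cells growing in 2% PPYS medium to 250000 cells per ml were pulse-labelled for 5 min with the thymidine analogue bromodeoxyuridine (BrdU), chased for 5 min with thymidine and given a final thymidine addition for 20 min. The labels give 2 concentration schemes without tying either to a sample: 100 µM BrdU, 50 µM and then 1 mM thymidine, or 500 µM BrdU, 250 µM and then 2 mM thymidine. Genomic DNA was sequenced on a MinION nanopore instrument from ligation libraries, per the labels' protocols. On such long reads, stretches of BrdU can be read along single molecules, and the positions and directions of replication forks follow from them.

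The authors deposited 1 list of 5160 intervals with 3 columns per line: a chromosome name, a start position and an end position in base pairs. The list gives no score, strand, kind of event, read or sample, so the intervals of both samples could only be analysed together, and the authors' value for an interval is its position. The submitters' processing notes name minimap2 and SAMtools, without versions. The step that called the intervals, its thresholds, the genome build and any filter are not given in the sources used here. The series title concerns replication initiation. The intervals are therefore called intervals below, and whether each one marks an initiation event is not stated in the file. Positions are printed 1-based in the coordinates of that list. The reference table at hand belongs to another assembly (JCVI-TTA1-2.2) with other sequence names, so no gene, intergenic region or base composition was assigned, and the tests planned for genes, gene lists and base composition were not run. Tests by event kind and of overlap between replicates were not run either, because lines carry neither label.

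Chromosome lengths were not given, so the extent of a chromosome was taken from base 1 to the end of its last interval. Because that interval sets the extent, it was left out of counts per chromosome and held in place in random placement; if intervals fall evenly, the remaining ones are then spread in proportion to the extent. Only the side at base 1 was taken as a chromosome end. The planned measure of distance to the nearer of both ends was replaced by distance from base 1.

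An interval was represented by its midpoint. Counts per chromosome were compared with extent by a Monte Carlo chi-square test with 10000 multinomial draws, followed by a two-sided exact binomial test per chromosome. Clustering and position were compared with 10000 random placements that kept each interval on its chromosome and at its length; this placement permutation test is two-sided and was adjusted over 6 tests. Bins of 10 kb were tested by the exact Poisson upper tail with the chromosome mean. All adjustments were by Benjamini-Hochberg with a threshold of 0.05. Alternatives used 2000 placements, pair distances 1000. Intervals on counts and ratios are exact 95% Poisson intervals unless named otherwise, and cover counting error only. For counts of pairs they can be too narrow, because an interval of the list can enter several pairs. With no read numbers in the list, the sequencing depth and the read coverage of each region are unknown, and random placement assumes even coverage. P-values measure departure from random placement in 1 pooled list, not variation between the samples, which the labels do not describe as separate cultures. All these tests treat intervals as independent. The grouping of intervals within stretches of the list, described below, can make their p-values too small.

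The rule for named items, fixed before the data were examined, was the 10 bins of 10 kb with the most midpoints, the chromosomes past the adjusted threshold, and the longest and shortest interval. Other named chromosomes were chosen after their values were seen. The list runs through the chromosome numbers repeatedly; it was broken into 31 stretches wherever the number fell, and these stretches were used only as a technical grouping. They are not samples. Nothing in the file says what they are.

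The scripts were tested on simulated data. Tests of spacing on simulated lists used 300 placements and an unadjusted threshold of 0.05, unlike the main tests. With the 5160 real lengths placed at random, 8 of 100 lists passed the test of midpoints within 1 kb of another. In other lists, 5% of intervals were chosen to move to 100 sites, with an SD of 300 bp around each site. A chosen interval moved only if its chromosome held a site, so fewer moved. Of these lists, 91 of 100 passed the test within 1 kb, but only 20 passed the test of the median distance and 19 that of the share within 5 kb. With 10% of intervals chosen and 100 sites, 100, 50 and 54 lists passed these 3 tests, and with 10% chosen and 500 sites, 100, 76 and 82. When 5 chromosomes with extents over 300 kb were simulated at 2 times the density of the other chromosomes, 85.6% of them were recovered over 50 simulated lists. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3. Alternatives covered the point that represents an interval, long intervals, the placement, the chromosomes used, bin size and offset, and the distances counted as near.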

Results

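In this series, whose title concerns replication initiation, BrdU-labelled DNA of vegetatively growing *Tetrahymena* (2 samples of 1 group) was read on single nanopore molecules. The pooled list held 5160 intervals on 179 chromosomes, numbered up to 180. Chromosome 109 had none. The extents of the chromosomes ranged from 24.96 to 3323 kb with a median of 373 kb, and summed to 99.4 Mb, or 1 interval per 19.3 kb. With 1 group, the design implied no comparison between conditions, and the positions were compared with random placement.

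Most intervals were short. Their median length was 511 bp (quartiles 366 and 756 bp), the mean was 699 bp with an SD of 687 bp over the 5160 intervals, and 85.2% were under 1 kb. At the upper end, 186 intervals (3.6%) measured 2 kb or more. The longest measured 9301 bp, on chromosome 73 from 526578 to 535878. The shortest, of 130 bp, lay on chromosome 23 from 929314 to 929443. No interval was listed more than once, and together they covered 3544 kb, or 3.56% of the summed extents.

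Interval density was highest on the chromosomes with extents under 200 kb. The mean was 5.01 intervals per 100 kb. Chromosomes with extents under 200 kb had 5.90 per 100 kb (95% Poisson interval 5.23 to 6.63; 283 intervals on 50 chromosomes). Those of 200 to 500 kb had 5.16 (4.85 to 5.49), those of 500 to 1000 kb 4.79 (4.52 to 5.07), and those over 1000 kb 4.98 (4.78 to 5.18). The 4 classes, which were not part of the planned tests, differed by more than independent draws in proportion to extent (Monte Carlo chi-square 11.0 on 3 degrees of freedom, p = 0.0099). The shortest class, set against the rest after the data were seen, had 1.19 times the density of the other classes together (exact binomial test, p = 0.00604). Both tests treat intervals as independent, so grouped intervals can make these p-values too small. The ratio was 1.14 with 10 kb trimmed from each side (exact binomial test, p = 0.0683), 1.01 with 20 kb trimmed (p = 0.897) and 1.08 with a limit of 300 kb in place of 200 kb (exact binomial test, p = 0.0636), while a limit of 150 kb gave 1.305 (p = 0.0001).

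Counts on single chromosomes also departed from proportionality to extent (chi-square 255.7 on 178 degrees of freedom, Monte Carlo p = 0.0003), but no single chromosome passed the adjusted threshold in the exact binomial test. At an unadjusted p under 0.05 stood 12 chromosomes, 7 above and 5 below their expected count. Chromosome 137, chosen after its values were seen, came closest. It held 24 intervals where 10.8 were expected, a ratio of 2.22 and a density of 11.1 per 100 kb (7.14 to 16.6; adjusted p = 0.066 in the exact binomial test). Among the larger chromosomes, chromosome 73 held 76 against 57.7 expected (exact binomial test, adjusted p = 0.465) and chromosome 124 held 38 against 55.0 (adjusted p = 0.465). Chromosome 71 held 13 against 25.7 (adjusted p = 0.370 in the exact binomial test). Chromosomes 152 and 165, with extents of 33.6 and 28.2 kb, had 7 and 6 intervals against 1.69 and 1.41 expected (exact binomial test, adjusted p = 0.160 and 0.197). When the last interval of each chromosome, which sets its extent, was counted too, chromosomes 137, 152 and 165 passed the exact binomial test (adjusted p = 0.0411, 0.0411 and 0.0473). That setting adds 1 interval to every chromosome, which raises the ratio most on the shortest ones by construction. Among the chromosomes over 100 kb alone, the chi-square test gave p = 0.0988, while chromosome 137 passed the exact binomial test there (adjusted p = 0.0493) and with 10 kb trimmed from each side of every chromosome (adjusted p = 0.0442).

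**Figure D1:**
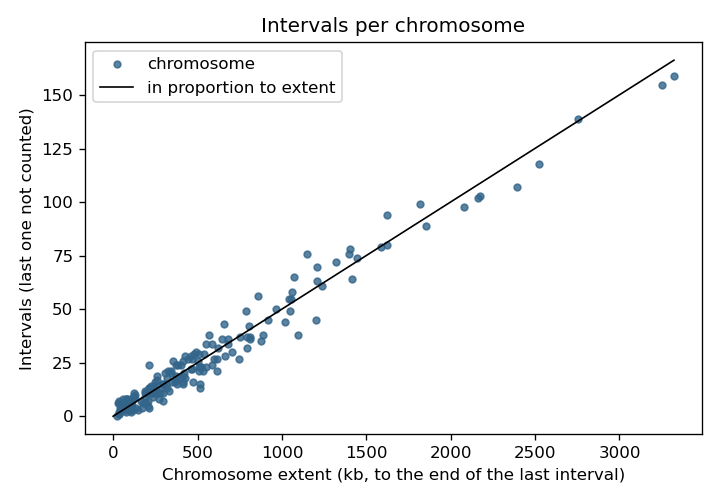
Number of intervals (last one of each chromosome not counted) against chromosome extent in kb, 1 point per chromosome for 179 chromosomes. The line marks proportionality at 5.01 intervals per 100 kb, and the points follow it up to the largest extent of 3323 kb.

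Across the pooled list, 4 measures of spacing did not differ detectably from random placement. The median distance from a midpoint to the nearest other was 6912 bp against 6907 bp in random placement (SD 160 over placements). Midpoints within 1 kb of another made up 9.61% of the list, against 9.66% in random placement (95% of placements between 8.57% and 10.8%). Within 5 kb the share was 39.2% against 39.6% (38.0% to 41.2%). Intervals that overlapped another by 1 bp or more made up 6.69%, against 6.82% (5.91% to 7.77%). Each of these 4 measures had an adjusted p = 0.973 in the placement permutation test. No position was covered by more than 3 intervals, and a depth of 3 was reached at 8 places, among them chromosome 21 at position 179124 and chromosome 120 at position 9306. An excess of recurrent sites that would lift the share within 1 kb above the placement range was not detectable in this list. In simulated lists with 10% of intervals chosen to move to 500 sites that share averaged 14.8%.

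Intervals in the same stretch of the list lay 5 to 20 kb apart more often than random placement gives, while pairs of different stretches at these distances did not pass the test. Same-stretch pairs 5 to 10 kb apart numbered 215 against 146 (ratio 1.47, 95% Poisson interval 1.28 to 1.68), and those 10 to 20 kb apart 461 against 286 (1.61, 1.47 to 1.77), each with adjusted p = 0.012 in the placement permutation test over the 18 distance classes tested. From 20 to 50 kb the ratio was 1.19 (permutation test, adjusted p = 0.012). Between different stretches the ratios at 5 to 10 and 10 to 20 kb were 1.04 and 0.975 (permutation test, adjusted p = 0.492 and 0.511). Different-stretch pairs under 0.1 kb apart numbered 34 against 23.3 (ratio 1.46, 95% Poisson interval 1.01 to 2.04). They did not pass the adjusted threshold (permutation test, adjusted p = 0.132). At 0.1 to 0.5 and 0.5 to 1 kb these ratios were 0.990 and 0.910. The stretches were looked at only after the data were seen.

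**Figure D2:**
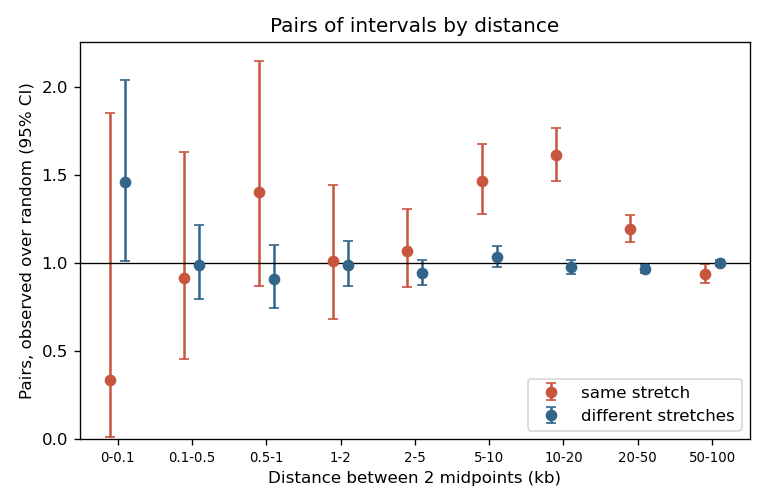
Ratio of observed to randomly placed pairs of midpoints by distance in kb, for pairs within 1 stretch of the list and pairs of different stretches, with 95% Poisson intervals. The same-stretch points at 5 to 10 kb (1.47) and 10 to 20 kb (1.61) lie above 1, while those of different stretches lie at 1.04 and 0.975.

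Counts in 10 kb bins also lay close to random placement. Of 10034 bins, 4079 (40.7%) held at least 1 midpoint, and 5955 held none against 5982 in random placement. Bins with 1 midpoint numbered 3155 against 3118, bins with 2 numbered 788 against 782, and bins with 3 numbered 117 against 133. The 19 bins with 4 or more compared with 19.4 in random placement. The ratio of variance to mean was 0.975 at 10 kb (random mean 0.992) and 1.09 at 50 kb (random mean 1.01), with permutation adjusted p = 0.282 and 0.062 over the 5 bin sizes tested. No 10 kb bin passed the adjusted threshold in the Poisson test, while 165 had an unadjusted p under 0.05; 12 of 1000 random placements gave at least 1 call.

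**Figure D3:**
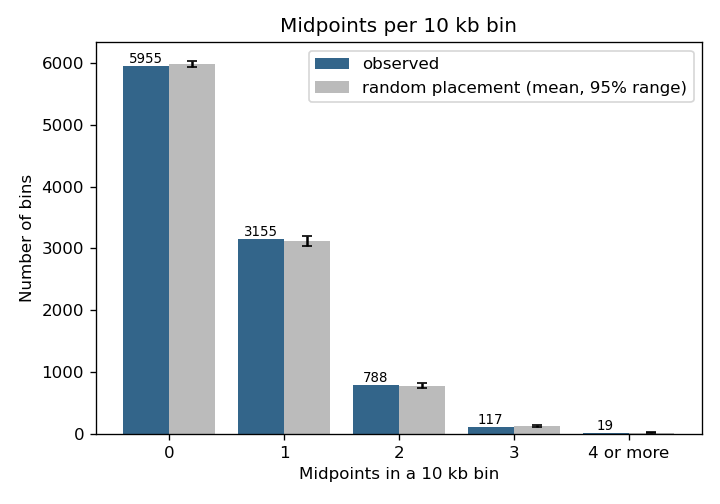
Number of 10 kb bins by the midpoints they held, observed (labelled bars) and in random placement (grey bars, mean with the range of 95% of placements). The observed bars, such as 788 bins with 2 midpoints, lie within the error bars of random placement in all 5 classes.

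The 2 fullest bins held 5 midpoints each. Chromosome 120 from 10001 to 20000 had 5 where 0.550 were expected, all within 2.48 kb and from 5 stretches of the list (adjusted p = 1 in the exact Poisson test). Chromosome 73 from 530001 to 540000 had 5 where 0.669 were expected, spread over 5.94 kb (exact Poisson test, adjusted p = 1). A count of 4 was reached by 17 bins. The 8 of these with the lowest Poisson p were named, at chromosome 66 from 1450001, chromosome 99 from 150001, chromosome 60 from 20001, chromosome 33 from 210001, chromosome 119 from 410001, chromosome 177 from 710001, and the first 10 kb of chromosomes 120 and 111. Their Poisson p-values ran from 0.00147 to 0.0033 before adjustment. The left side of chromosome 120 thus appeared in 2 neighbouring bins. When the bins were shifted by 5 kb, as planned, the region from 5001 to 15000 of chromosome 120 held 8 midpoints from 6 stretches against 0.550 expected and passed the exact Poisson test (adjusted p = 0.0013). With 20 kb bins, positions 1 to 20000 of that chromosome held 9 against 1.10 (exact Poisson test, adjusted p = 0.012). These were the only calls in either setting, and 3 and 5 of 500 random placements, respectively, gave a call.

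Near base 1 of the chromosomes intervals were absent at first and then frequent. The first 10 kb held 129 midpoints, on 96 chromosomes, against 95.8 in random placement (SD 9.52), a ratio of 1.35 (permutation test, adjusted p = 0.0096). No interval began before position 1843, on chromosome 26, and the first 2 kb held no midpoint where random placement gave 16.5 (permutation test, p = 0.0002, the smallest that these placements can give). From 2 to 10 kb there were 129 against 79.3, a ratio of 1.63 (permutation p = 0.0002, also the smallest possible). The limit of 2 kb was set after the values were seen. The counts were highest from 4 to 5 kb, with 25 midpoints against 9.95 (ratio 2.51, 95% Poisson interval 1.63 to 3.71), from 5 to 6 kb, with 22 against 9.93 (2.21, 1.39 to 3.35), and from 7 to 8 kb, with 21 against 9.89 (2.12, 1.31 to 3.24). From 10 to 15 kb the ratio was 1.25 (0.959 to 1.60), and from 20 to 30 kb it was 1.02 (0.832 to 1.24). With the last interval of each chromosome placed like the others, the ratio for the first 10 kb was 1.22 (permutation test, adjusted p = 0.078). That setting spreads intervals that by definition lie at the far side, which raises the random count near base 1 by construction.

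**Figure D4:**
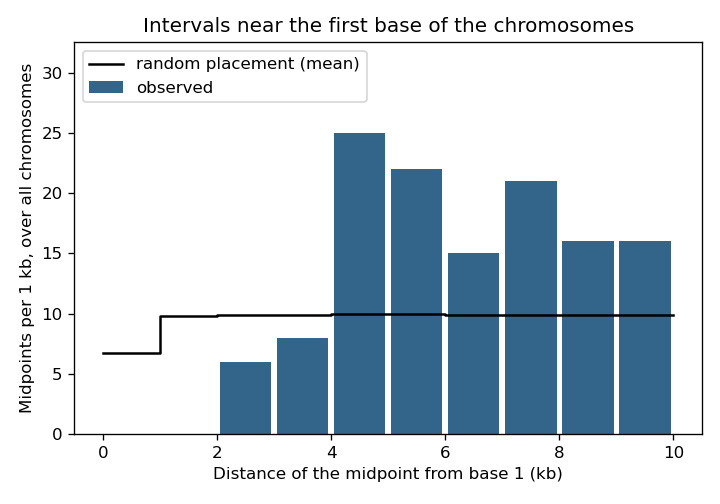
Midpoints per 1 kb of distance from base 1, summed over 179 chromosomes (bars), with the mean of random placement as a line. The first 2 kb are empty, and the bar from 4 to 5 kb reaches 25 against 9.95 in random placement.

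Away from base 1 no part of the chromosomes passed the test. The median position was at 49.8% of the extent against 50.0% in random placement (SD 0.710, permutation test, adjusted p = 0.973). Of the 10 equal parts of the extent, the first held the most relative to random placement, with 536 midpoints against 495 (permutation p = 0.0576), and the ninth the fewest, with 463 against 499 (p = 0.0902). Within 10 kb of the end of the last interval there were 103 midpoints against 95.8 (permutation p = 0.476). That side lies an unknown distance from the true chromosome end.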

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

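Of 53 alternative values of the main results, 40 kept their direction and their side of the threshold or stayed within 1.5 times a count. None of the 4 spacing measures passed the threshold under the alternatives run, which for the overlapping share were added after seeing the data. Their ratios to random placement lay near 1, and crossed it with interval starts (1.05 for the share within 1 kb), without the longest 10% of intervals (1.01 for the overlapping share) and with placement over the whole genome (0.993 for the median distance, 1.01 for the share within 1 kb). The excess in the first 10 kb kept its call under the alternatives run, with these exceptions. The first 5 kb alone gave a ratio of 0.843, since they include the empty first 2 kb. Placing the last interval like the others, an alternative added after seeing the data, gave 1.22 (adjusted p = 0.078 in the placement permutation test). It also turned the median position to a ratio of 1.03. By construction, that placement lowers the ratio near base 1 and raises that of the median position. The chi-square over its degrees of freedom fell from 1.44 to 1.15 (p = 0.0988) on chromosomes over 100 kb. Trimming 10 kb from each side called 1 chromosome and the chromosomes over 100 kb also 1, chromosome 137 in both. Counting all intervals, also added later, called 3 (137, 152 and 165), but it raises short chromosomes by construction. The density ratio of chromosomes under 200 kb lost its call with 10 kb trimmed (1.14), 20 kb trimmed (1.01) and a limit of 300 kb (1.08), and kept it with a limit of 150 kb (1.305) and on chromosomes over 40 kb (1.15), all added later. Shifted bins called 1 bin and 20 kb bins 1, both at the left side of chromosome 120. No identical intervals existed, so counting them once changed nothing. Leaving out a replicate was not possible. No paired analysis was possible because the lines name no sample and there is 1 group. Alternatives for genes, gene lists, base composition and event kinds were not run. Even read coverage was assumed throughout.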

Other observations

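The 3 patterns below were noticed in the data. The test of pairs under 5 kb was chosen after its result was seen, while the predictions of the other tests were written before their results. The comparison over chromosomes above 40 kb was added later, and that with an even excess was not in the predictions either. Every one of these tests was added after the data were examined.

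Same-stretch pairs of intervals 5 to 20 kb apart exceeded random placement. Under 5 kb the ratio was 1.07 (0.907 to 1.25), below the 1.56 (1.45 to 1.69) at 5 to 20 kb. Uneven read coverage within a stretch would raise close pairs too, if the calling step returned them as freely as distant ones. That step is unknown and the test was chosen after its result was seen, so uneven coverage was not excluded. A few stretches did not carry the pattern: without the 3 with the largest excess the ratio was 1.54 (1.38 to 1.72). A candidate explanation is that some molecules contributed several intervals at least about 5 kb apart. Both predictions written for it failed: the ratio was 1.49 (1.37 to 1.62) for neighbours by position against 2.13 (1.73 to 2.58) for pairs with another interval between them, and 1.38 (1.265 to 1.503) on adjacent lines against 3.04 (2.57 to 3.58) on lines further apart. Neighbours made up 77.9% of the 244 excess pairs, below the 88.9% in random placement. The split by position cannot decide, because both classes exceeded random placement. A molecule with several intervals also gives pairs with another between them, and intervals of other molecules can fall between 2 of one molecule. The split by lines cannot decide either, because 15.6% of adjacent lines on a chromosome ran backwards, whereas the random lists were sorted. The explanation stays open. No biological explanation was tested.

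The excess from 2 to 10 kb did not rest on the 5 chromosomes with the most midpoints there, and was seen in both odd and even stretches. The gap in the first 2 kb was not tested in this way. Without the 5 chromosomes with the most midpoints there the ratio from 2 to 10 kb was 1.47 (1.21 to 1.77). In the odd and even stretches it was 1.53 (1.18 to 1.95) or more. This split mixes early and late stretches, so it cannot exclude that a run of neighbouring stretches carried the excess. Without the longest 10% of the intervals it was 1.69 (1.41 to 2.02). That removal could hardly change the ratio, because 121 midpoints remained from 2 to 10 kb, against 129 in the full list. Random placement also kept each interval at its length and inside its chromosome. The removal therefore cannot decide whether long intervals play a part. Read coverage and the calling step near the ends of reads and chromosomes remain open, since the list holds neither, and no biological explanation was tested.

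The density on chromosomes under 200 kb was 1.19 times that of the other chromosomes (1.05 to 1.34, exact binomial interval). A candidate explanation is that an excess near chromosome ends weighs more on short chromosomes. With 10 kb trimmed from each side, which drops no chromosome, the ratio was 1.14 instead of 1.19 and lost its call (exact binomial test, p = 0.0683). With 20 kb trimmed from each side the ratio was 1.01 (0.847 to 1.19). This met the written prediction, an interval including 1 and an estimate nearer 1, but the trim drops the 7 chromosomes of 40 kb or less. The untrimmed ratio of the remaining ones was 1.15 (1.007 to 1.298). The intervals of these ratios, 1.01 and 1.15, overlap, so the explanation stays open. Without the 3 chromosomes with the largest excess the ratio was 1.13 (0.993 to 1.28). This met the prediction written for a few chromosomes, an interval including 1. An even excess would give 1.12 (1.09 to 1.14) after the same removal, so a few chromosomes and an even excess cannot be told apart.

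Interval lengths differed between stretches (permutation p = 0.0001, the smallest that 10000 permutations can give). Among the 22 stretches with at least 50 intervals, the median length ran from 415 bp in one of 126 intervals to 643 bp in one of 863.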
